A study of Arabidopsis thaliana with 6 samples.

How the data were processed

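Transcript levels were measured by RNA sequencing in whole Arabidopsis thaliana seedlings of 2 genotypes, the wild-type accession Col-0 and the gi-2 mutant of GIGANTEA (GI), with 3 biological replicates each. Per the labels' protocols, seedlings grew for 7 d on 0.5x MS medium in short days of 8 h light and 16 h dark at 22 °C and 80 µmol m-2 s-1, and pools of 40 to 60 were frozen at ZT0, the time of lights-on. Total RNA was treated with DNase and made into non-directional cDNA libraries with inserts of 250 to 300 bp, per the labels' protocols. The labels do not state whether replicates came from separate days, so p-values measure the spread between these pools.

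The authors deposited raw read counts per gene, 1 whole number per gene and library, with no scaling. STAR 2.5.5, HTSeq 0.6.1, DESeq2 and the TAIR10 build are named for the series, per the submitters' processing notes. The strand and multi-mapping settings of the counting are not given in the sources used here. Because the libraries carry no strand, reads of overlapping or antisense genes cannot be told apart, and closely related paralogs may share or lose reads. Among the named genes, other annotated genes overlap CO, FAR1, XTH15, RVE1, ELF3, FKF1, CPD, BES1, ABI1, PORB, BAM3, MCCA, CHS, DREB2A, CAT2, COL2, BBX25, PYK10, CASP1 and PP2-A1, whose values are uncertain to that extent. The table held 32833 genes, of which 8687 had no count in any library, and 0 rows named no gene. In 24 rows the annotation columns were shifted by spaces within gene names and were read around, with the counts intact. Gene positions are those of the deposited table, in TAIR10 coordinates. The start and end of 32508 of 32524 nuclear genes were identical in the RefSeq TAIR10.1 annotation, which was used for symbols and product names.

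Library totals were 21675676, 23617717 and 20071825 counts in gi-2 replicates 1, 2 and 3, and 18739317, 20225315 and 19738165 counts in Col-0 replicates 1, 2 and 3. A floor of 3 counts corresponded to 0.127 to 0.160 CPM (counts scaled to a common library size). Confidence intervals are exact binomial intervals at 95%. Such intervals and floors cover counting error only. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.96 to 15.6, so each library was counted as 1 sample.

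The comparison of gi-2 with Col-0 used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (minimum count 10, minimum total 15), and the quasi-likelihood F test with genotype as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The submitters' notes name DESeq2, which was run as an alternative here. CPM values are TMM-scaled and given as mean ± SD over 3 replicates. Each standard error (SE) of a log2 fold change is the one implied by the F statistic. On simulated counts for 19699 genes with 200 changed, the test recovered 46% of changes of 1.5-fold and 89% of changes of 2-fold. Those counts were drawn with the means and library sizes of gi-2 against Col-0 and 1 common spread for all genes. Of the 144 calls on them, 9 were false. The real comparison called 32.6% of genes, a far larger share than was changed in the simulation, so these rates need not hold for it.

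Gene lists were compared with all other genes by camera in limma 3.58.1 (log2 CPM with a prior count of 2, preset correlation 0.01), adjusted over 31 lists with at least 3 measured members. The lists hold 459 genes, all found in the table, but members that failed the low-count filter were not measured. Measured were 13 of 23 flavonoid, 11 of 18 heat shock and 16 of 21 jasmonate genes. For salicylic acid it was 16 of 20 and for gibberellin 15 of 20. Unless stated, counts of list members below are of measured genes. They cover morning and evening clock genes, promoters and repressors of flowering, genes of phytochrome-interacting factors (PIFs) and PIF targets, growth-related SAUR genes, auxin, gibberellin, brassinosteroid, abscisic acid, jasmonate and salicylic acid genes, and cold, heat and reactive oxygen genes. Others cover light-harvesting antennae, chlorophyll synthesis with GLK regulators, light-induced genes, starch, sugar starvation, flavonoids, aliphatic glucosinolates, B-box genes, the mitotic cell cycle, and markers of root hairs, inner root, vasculature, stomata, trichomes and seeds. Some genes stand in more than 1 list.

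The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. Named genes were GI, CCA1, LHY, TOC1, CO and FT in any case. They further included the 8 genes higher and 8 lower with the largest log2 fold change among those past the threshold, with an average log2 CPM of at least 1 and no overlap between genotypes. The up to 4 members with the smallest adjusted p past the threshold were taken from the morning clock, evening clock, flowering promoter, flowering repressor and PIF target lists, and up to 2 from every other list. Further list members are given as examples and were chosen after their values were seen.

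Alternatives were size factors by the DESeq2 method, library size alone, no filter, a mean CPM of at least 1, leaving out each library in turn, the replicate number as a block, nuclear genes only, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, a minimum change of 1.5-fold by glmTreat, offsets for GC content and length (available for 99.4% of tested genes), camera with an estimated correlation, and fry. Leaving out both gi-2 replicate 2 and Col-0 replicate 1 was added after seeing the data. Figures were drawn with matplotlib 3.10.9.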

Results

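RNA was counted per gene in 6 libraries of whole seedlings at lights-on (ZT0), 3 from the gi-2 mutant and 3 from wild-type Col-0. GI encodes a clock-controlled protein that acts in the circadian clock and in the photoperiodic control of flowering, and gi-2 is a mutant allele of it. Between 18739317 and 23617717 counts were assigned to genes per library, and 21345 to 22308 genes had at least 1 count. Chloroplast genes took at most 0.103% and mitochondrial genes at most 0.0562% of the counts. The antenna gene LHCB1.3 was the most abundant in each library, with 5.06% to 5.45% of the counts in gi-2 and 4.05% to 4.1% in Col-0.

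GI transcript itself, from the mutated gene (AT1G22770, chromosome 1, 8061751 to 8067790), was present in gi-2 and more abundant than in Col-0. The 3 gi-2 libraries held 183, 210 and 139 GI counts and the 3 Col-0 libraries 68, 59 and 53. GI stood at 8.02 ± 0.95 CPM in gi-2 and 3.11 ± 0.576 CPM in Col-0 (SD, n = 3 each), a log2 fold change of 1.37 (SE 0.21; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000168). The level of a transcript counted over the whole gene does not show whether the allele makes protein, so it checks the labels only in that the genotypes differ.

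The first question was how many transcripts differ between gi-2 and Col-0 at dawn. Of 19699 genes tested, 3214 were higher and 3199 lower in gi-2, together 32.6% (edgeR). Most changes were small. The median absolute log2 fold change of the changed genes was 0.56, and 617 higher and 534 lower genes exceeded 2-fold, while 141 and 87 exceeded 4-fold. The libraries of the genotypes did not overlap for 8920 genes (45.3%, where chance gives 10%), which include 6263 of the 6413 changed genes. A principal component with 56.6% of the variance parted the genotypes, and the next, with 17.5%, set Col-0 replicate 1 apart from the other Col-0 libraries. Without gi-2 replicate 2 and Col-0 replicate 1, chosen after seeing the data, 6296 genes were called.

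Among the genes with the largest increases in gi-2 were IRT3 (AT1G60960), a metal transporter of the ZIP family, at 45.0 ± 3.18 against 0.762 ± 0.537 CPM, and the fatty acyl reductase gene FAR1 (AT5G22500), at 177 ± 38.9 against 10.9 ± 0.320 CPM. Their log2 fold changes were 5.85 (SE 0.24) and 4.02 (SE 0.15). QQS (AT3G30720), a regulator of starch content, and XTH15 (AT4G14130), a cell wall xyloglucan enzyme, both rose by 3.83 on the log2 scale. The uncharacterized gene AT1G75945 had 338 counts in gi-2 and 1 in Col-0, a ratio of 304 with a counting interval of 54.1 to 12020. Without Col-0 replicate 3 the log2 fold change of IRT3 was 6.57, and AT1G75945 had 0 counts in Col-0, at least 67.2-fold higher in gi-2 against a floor of 3 counts over the group. Without Col-0 replicate 1 the log2 fold change of QQS was 4.65.

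The remaining genes of that set were the seed storage genes CRU3 and CRA1 and the uncharacterized AT1G68250, whose levels were set mostly by gi-2 replicate 2. CRU3 (AT4G28520) reached 81.8 CPM in that library against 2.27 and 11.7 CPM in gi-2 replicates 1 and 3, and CRA1 (AT5G44120) reached 261 CPM against 13.6 and 46.2 CPM. Without gi-2 replicate 2 the log2 fold change moved from 8.45 to 6.24 for CRU3 and from 4.49 to 2.65 for CRA1, both still past the threshold. For AT1G68250 it moved from 6.79 to 1.67 (edgeR adjusted p = 0.142 without that library). The adjusted p of AT1G68250 ran from 3.16e-05 to 0.377 over the edgeR and limma-voom alternatives, and DESeq2 gave it none. Without Col-0 replicate 3 the log2 fold changes were 5.48 for CRA1 and 7.93 for AT1G68250, while CRU3 had 0 counts in Col-0, at least 445-fold higher in gi-2 against the same floor. Limma-voom did not call CRU3 (adjusted p = 0.144; 1.40e-07 to 0.144 over all alternatives) or CRA1 (adjusted p = 0.0758; 9.57e-07 to 0.0758).

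Among the largest decreases under the rule for named genes were those of AT1G26790, a Dof-type transcription factor gene, at 0.120 ± 0.108 CPM in gi-2 and 11.9 ± 2.61 CPM in Col-0 (log2 fold change -6.54, SE 0.41), and of the uncharacterized AT3G01345 (-6.20, SE 0.40) and AT2G15020 (-4.63, SE 0.30). AT1G26790 had 0, 5 and 3 counts in gi-2 replicates 1, 2 and 3, near the floor, so the size of its fall is uncertain. Without gi-2 replicate 2 the values of AT1G26790 and AT2G15020 were -7.26 and -5.23. CYP79F1 (AT1G16410) and FMO GS-OX3 (AT1G62560), both of aliphatic glucosinolate synthesis, fell by 5.22 and 3.35. SQP1 (AT5G24150), a squalene monooxygenase-like gene, fell by 3.69 on the log2 scale. The plastid phosphoenolpyruvate translocator gene PPT2 fell by 3.3 and the lipid transfer protein gene LTP6 fell by 3.22.

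Clock genes moved in opposite directions by their time of peak. Of 13 morning clock genes, 10 were lower and 2 higher in gi-2, with the same counts adjusted over the list alone. LHY (AT1G01060, chromosome 1, 33365 to 37871), a core dawn transcription factor, stood at 235 ± 1.68 CPM in gi-2 and 827 ± 14.3 CPM in Col-0, a log2 fold change of -1.81 (SE 0.07; edgeR adjusted p = 4.82e-10). Its partner CCA1 (AT2G46830, chromosome 2, 19245591 to 19248915) fell by 1.25 (SE 0.08; edgeR adjusted p = 3.84e-08) and RVE1, a related factor of auxin control, by 1.01. PRR7, a daytime repressor of CCA1 and LHY, rose by 1.94 and RVE7 by 0.84, against the list's direction, and PRR9 did not pass (0.32, SE 0.26). The list median was -0.87 (camera adjusted p = 0.000917; adjusted p = 0.175 with an estimated correlation).

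Of 10 evening clock genes and outputs, 9 were higher in gi-2, and 10 adjusted over the list alone. TOC1 (AT5G61380, chromosome 5, 24674963 to 24678550), an evening repressor, stood at 46.3 ± 2.33 against 17.9 ± 1.80 CPM (log2 fold change 1.37, SE 0.10; edgeR adjusted p = 1.90e-07). PRR5 rose by 3.28 (SE 0.34), the clock output GRP7 by 1.80 (SE 0.09) and ELF3, of the evening complex, by 1.09 (SE 0.08). FKF1, which binds GI in the control of flowering, had 0 counts in Col-0 and 63 in gi-2, at least 18.9-fold higher against a floor of 3 counts over the group. The list median was 1.59, also with FKF1 at that bound (camera adjusted p = 9.00e-08; adjusted p = 0.113 with an estimated correlation). Without Col-0 replicate 2 the bound for FKF1 was 12.4-fold. Reads of FKF1 and ELF3 are uncertain, since other annotated genes overlap them.

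**Figure D1:**
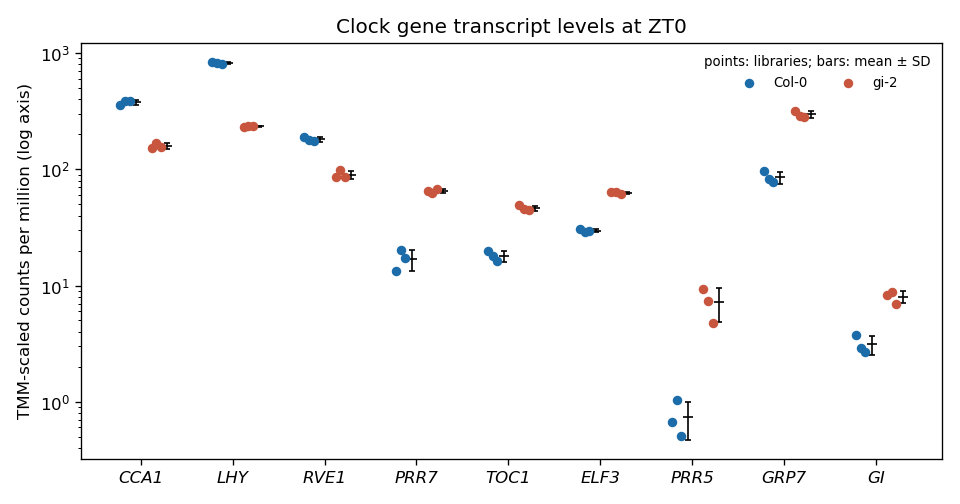
Transcript levels of 9 clock genes at ZT0 in TMM-scaled CPM on a log axis, with a point per library and the mean and SD of 3 libraries beside the points. CCA1, LHY and RVE1 lie lower in gi-2 than in Col-0, and PRR7, TOC1, ELF3, PRR5, GRP7 and GI lie higher, with no overlap between the genotypes.

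Whether flowering genes differed at this time was limited by their low counts. Of 13 promoters of flowering, 4 were measured, and 2 of these were higher, with the same count adjusted over the list alone (median log2 fold change 0.92; camera adjusted p = 0.0819). FT (AT1G65480), the mobile flowering signal, had 0 counts in all libraries. CO (AT5G15840), the photoperiod regulator that activates FT, had a log2 fold change of 1.07 (SE 0.78, edgeR adjusted p = 0.327, and 0.0303 to 0.783 over the alternatives that tested it). Without Col-0 replicate 3 the log2 fold change of CO was 2.94 (edgeR adjusted p = 0.0303). Its reads are uncertain, since annotated genes overlap CO. FKF1 and SOC1 were the promoters called, SOC1 with a rise of 0.77 (SE 0.24). The SOC1 call was lost without gi-2 replicate 2 (edgeR adjusted p = 0.0919), gi-2 replicate 3 (0.0694) or Col-0 replicate 2 (0.0559), in a range of 0.0213 to 0.133 over all alternatives. Without gi-2 replicate 1 the promoter list passed the test (camera adjusted p = 0.0449).

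Of 18 repressors of flowering, 5 were higher and 5 lower, adjusted over all genes. TEM1 and SVP, repressors of FT, rose by 0.89 and 0.88, and CDF1, a repressor of CO, and the AP2-like SNZ fell by 1.1 and 1.31. FLC, the vernalization-controlled repressor, fell by 0.81 (SE 0.18). Adjusted over the list alone, 5 were higher and 5 lower as well. Their median was 0.23 while the mean was -0.03, and the list as a whole did not differ from other genes (camera adjusted p = 0.888).

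Growth-related genes of the PIF pathway were mostly higher. Of 21 genes induced by PIFs, 14 were higher and 1 lower in gi-2, also adjusted over the list alone (median 0.47; camera adjusted p = 2.98e-05; adjusted p = 0.175 with an estimated correlation). ST2A, a jasmonate sulfotransferase gene, rose by 3.13 (459 ± 40.4 against 52.5 ± 8.02 CPM) and XTH15 stood at 480 ± 135 against 33.7 ± 7.24 CPM. YUC8, of auxin synthesis, rose by 1.39 and ACS8, of ethylene synthesis, by 1.51. PRE1 fell by 1.28. Among the 5 PIF genes, PIF4, PIF3 and PIF5 rose by 1.04, 0.86 and 0.20, PIF7 had a log2 fold change of -1.0 (SE 0.22), and PIF1 stood at -0.23 (SE 0.09); adjusted over the list alone PIF1 was also lower, and the list did not pass (camera adjusted p = 0.437). Of 6 SAUR genes of cell expansion, SAUR20 and SAUR21 fell by 1.03 and 0.79 and 4 did not pass, with 3 lower adjusted over the list alone (camera adjusted p = 0.0837). That list passed without gi-2 replicate 2 (camera adjusted p = 0.0359) or Col-0 replicate 1 (0.0436). These SAUR genes are close paralogs in tandem and their reads are uncertain.

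Early auxin-responsive genes rose in 11 of 20 cases and 1 fell, with the same counts adjusted over the list alone (median 0.46; camera adjusted p = 0.000531; adjusted p = 0.175 with an estimated correlation). IAA7 and IAA19, auxin-induced repressors, rose by 0.81 and 1.11, and IAA14 fell by 0.45. Of 15 gibberellin genes, 7 were higher and none lower over all genes and over the list alone (median 0.68; camera adjusted p = 0.00143; adjusted p = 0.175 with an estimated correlation). GID1A, a gibberellin receptor gene, rose by 1.05 and GA2OX6, of gibberellin inactivation, by 1.57. Without Col-0 replicate 2 the gibberellin list did not pass (camera adjusted p = 0.0530). Of 12 brassinosteroid genes, 6 were higher and 1 lower, with the same counts adjusted over the list alone: CPD, a synthesis gene, rose by 0.76 and the transcription factor gene BES1 fell by 0.63 (camera adjusted p = 0.219).

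Cold-regulated genes were higher as a group, with a stated growth temperature of 22 °C for both genotypes. Of 16 measured, 13 were higher and none lower, over all genes and over the list alone (median 1.4; camera adjusted p = 4.69e-09; adjusted p = 0.113 with an estimated correlation). COR414-TM1, of the chloroplast envelope or thylakoid, stood at 118 ± 3.03 against 20 ± 4.31 CPM (log2 fold change 2.55, SE 0.12), and the dehydrin gene COR47 at 564 ± 43.0 against 188 ± 16.2 CPM (1.58, SE 0.09). CBF1, a regulator of cold-induced genes, had 223 counts in gi-2 and 1 in Col-0, a ratio of 200 with a counting interval of 35.6 to 7945. Its tandem paralog CBF2 rose by 3.23 (SE 0.33) and CBF3 was not measured. Paralogs may share or lose reads, so the size of the rise of CBF1 alone is uncertain. Of 21 abscisic acid and drought genes, 10 were higher and 1 lower, and 10 and 2 adjusted over the list alone (camera adjusted p = 0.0615). ABI1 and HAB1 both encode phosphatases that dampen the hormone's signal, and ABI1 rose by 1.28 while HAB1 fell by 0.63. This list passed without gi-2 replicate 1 (camera adjusted p = 0.00836) or gi-2 replicate 3 (0.0400), with no low-count filter (0.0447), with a mean CPM of at least 1 (0.0440), and with the replicate block alone (0.0450) or with GC and length offsets (0.0495). It had an adjusted p of 0.213 without gi-2 replicate 2, the library with the most seed storage transcript.

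Genes of light response and chlorophyll synthesis were mostly lower. Of 13 genes induced rapidly by light, 10 were lower and none higher, and 11 lower and 1 higher adjusted over the list alone (median -1.22; camera adjusted p = 4.62e-06; adjusted p = 0.113 with an estimated correlation). SIG5, a plastid sigma factor gene, fell by 1.51 (SE 0.08) and HYH, a partner of the light regulator HY5, by 2.1 (SE 0.15). Of 15 genes of chlorophyll synthesis and its GLK regulators, 12 were lower and 2 higher, also over the list alone (median -0.84; camera adjusted p = 0.000203; adjusted p = 0.458 with an estimated correlation). GUN5, a subunit of magnesium chelatase, fell by 1.17 and HEMA1, which begins the pathway, by 1.01. PORB and PORA, protochlorophyllide reductases, rose by 1.79 (SE 0.08) and 2.53 (SE 0.52) while PORC fell by 0.93. PORA varied widely between the gi-2 libraries, at 13.3 ± 9.77 CPM. An annotated gene overlaps PORB.

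Light-harvesting antenna genes were lower in 10 of 19 cases and higher in 2, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.0989). LHCA6 fell by 1.29 and LHCB1.4 rose by 1.43. The LHCB1 genes are near-identical paralogs, so their single values are uncertain. Of 9 CONSTANS-like and other B-box genes, 5 were lower and 2 higher, also over the list alone (camera adjusted p = 0.0251; adjusted p = 0.307 with an estimated correlation). COL2 fell by 1.90 and BBX25 by 1.4. Without Col-0 replicate 1 the B-box list did not pass (camera adjusted p = 0.0537).

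Genes induced by darkness and sugar starvation rose in 14 of 15 cases and none fell, over all genes and over the list alone (median 1.35; camera adjusted p = 3.69e-10; adjusted p = 0.175 with an estimated correlation). DRM1, a dormancy-associated gene, stood at 509 ± 19.7 against 108 ± 2.92 CPM (log2 fold change 2.24, SE 0.07), and MCCA, of leucine breakdown, at 406 ± 19 against 96.9 ± 11.7 CPM (2.07, SE 0.09). ASN1, an asparagine synthetase gene, rose by 1.55 and DIN10 by 1.82. Starch genes went both ways, with 13 of 28 higher and 9 lower, and 14 and 9 adjusted over the list alone (camera adjusted p = 0.437). GBSS1, of amylose synthesis, fell by 2.37 (SE 0.08) and BAM3, a plastid beta-amylase gene, by 2.35 (SE 0.08). AMY3, ISA3 and PHS1, of starch breakdown, rose by 1.29, 1.32 and 1.14.

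**Figure D2:**
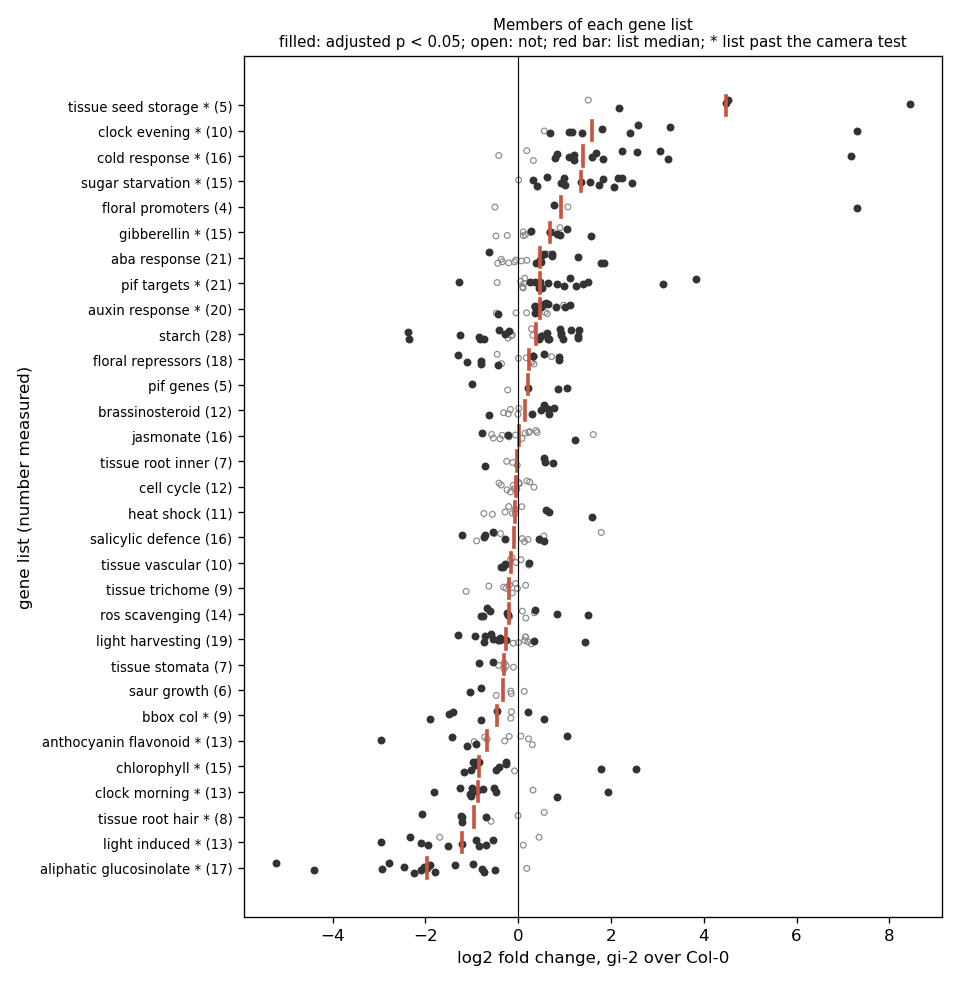
Log2 fold change of gi-2 over Col-0 for each measured member of the 31 gene lists, with filled points for genes past the edgeR threshold and a bar at each list's median. Medians run from -1.96 for aliphatic glucosinolate synthesis to 4.49 for seed storage, and lists with an asterisk passed camera with the preset correlation.

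Aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, was lower at nearly every step. Of 17 genes, 16 were lower, over all genes and over the list alone (median -1.96; camera adjusted p = 5.79e-11; adjusted p = 0.175 with an estimated correlation), and MAM3 did not pass (0.18, SE 0.27). CYP79F1 stood at 0.616 ± 0.107 CPM in gi-2 and 23.4 ± 7.46 CPM in Col-0, and MAM1, of side chain elongation, at 17.2 ± 1.01 and 73.3 ± 11.9 CPM. Their regulators MYB28 and MYB29 fell by 0.74 and 4.39. MYB29 stood at 0.138 CPM in gi-2, near the floor, so the size of its fall is uncertain. Of 23 flavonoid genes 13 were measured, and DFR, LDOX, PAP1 and PAP2 were not among them. Of the 13, 4 were lower and 1 higher, and 5 and 1 adjusted over the list alone (median -0.67, camera adjusted p = 0.0360, and 0.180 with an estimated correlation). CHS, the first committed enzyme, fell by 2.96 (SE 0.21) and MYBL2, a repressor of the pathway, rose by 1.06. Without Col-0 replicate 3 the flavonoid list did not pass (camera adjusted p = 0.0717).

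The lists of salicylic acid, jasmonate, heat shock and reactive oxygen genes did not pass camera. Salicylic acid genes were lower in 5 and higher in 2 of 16 cases, also over the list alone (camera adjusted p = 0.513), with ICS1, of salicylic acid synthesis, falling by 0.71 and ACD6 by 1.21. Jasmonate genes were lower in 2 and higher in 1 of 16, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.874), with VSP1 falling by 0.79 and CORI3 rising by 1.22. The jasmonate median was 0.01 while camera's direction was down. Heat shock genes were higher in 3 of 11, also over the list alone (camera adjusted p = 0.805), with DREB2A rising by 1.59 and HSFA7A by 0.67; their median was -0.07 and camera's direction up. Reactive oxygen scavenging genes were lower in 6 and higher in 3 of 14, and 8 and 4 adjusted over the list alone (camera adjusted p = 0.548). The catalase genes CAT3 and CAT2 moved apart, CAT3 rising by 1.51 and CAT2 falling by 0.81.

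Tissue markers were examined as a check on the make-up of the pools. Root hair and epidermis markers were lower in 5 of 8 cases, also over the list alone (median -0.95; camera adjusted p = 0.0166; adjusted p = 0.175 with an estimated correlation), among them the cell wall genes LRX1 and PRP3, which fell by 1.21 and 1.22. Inner root markers were higher in 3 and lower in 1 of 7, also over the list alone (camera adjusted p = 0.724): the endodermal CASP1 rose by 0.56 and PYK10, a root beta-glucosidase gene, fell by 0.72. Their median was -0.02 and camera's direction up. Vascular markers were lower in 3 and higher in 1 of 10, also over the list alone (camera adjusted p = 0.437), with PP2-A1 falling by 0.37 and SUC2 rising by 0.24. Stomatal markers were lower in 2 of 7, also over the list alone (camera adjusted p = 0.0615), with KAT1 falling by 0.54 and SPCH by 0.85. The stomatal list passed without gi-2 replicate 2 (camera adjusted p = 0.0224), with no low-count filter (0.0401), and with the replicate block alone (0.0292) or with GC and length offsets (0.0301). The SUC2 call was lost without gi-2 replicate 1 (edgeR adjusted p = 0.0744), 2 (0.0670) or 3 (0.0612) or Col-0 replicate 3 (0.0629), in a range of 0.0101 to 0.0744 over all alternatives. The SPCH call was lost without gi-2 replicate 1 (0.0592) or 3 (0.0839) or Col-0 replicate 1 (0.0529), in a range of 0.0160 to 0.0839.

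Seed storage and embryo genes were higher in 4 of 5 measured cases, and in 5 adjusted over the list alone (median 4.49; camera adjusted p = 0.0355; adjusted p = 0.536 with an estimated correlation). Its mean log2 CPM was 1.33, 4.66 and 2.1 in gi-2 replicates 1, 2 and 3 and -1.53, -0.33 and -0.05 in Col-0. Without gi-2 replicate 2 the median was 2.65 with 3 of 5 genes higher (camera adjusted p = 0.0277). Without Col-0 replicate 1 or 3 this list did not pass (camera adjusted p = 0.0745 and 0.0504), nor did it in fry (adjusted p = 0.0737). No trichome gene of 9 and no mitotic cell cycle gene of 12 passed in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.597 and 0.781). In all, 14 of 31 lists passed camera with the preset correlation and 0 with an estimated one, where 7 had an unadjusted p under 0.05, while 18 passed fry, which tests each list on its own, 13 of them shared with camera.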

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

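Leaving out both gi-2 replicate 2 and Col-0 replicate 1 was chosen after seeing the data, and the other settings were planned. At an adjusted p under 0.01, 4118 genes were called, 2028 higher and 2090 lower, and with a minimum change of 1.5-fold 1060, of which 546 were higher and 514 lower. Both settings ask for stronger evidence by construction. Leaving out 1 library at a time gave 4910 to 6687 changed genes (2365 to 3310 higher, 2545 to 3377 lower), a log2 fold change of GI of 1.27 to 1.52, and 12 to 16 gene lists past the threshold. Of the lists for harvest light and tissue make-up, 4 passed, and 3 to 5 with 1 library left out. With an estimated correlation 0 of all lists and 0 of these passed camera. Higher correlation alone does not account for this. The estimate was 0.0104 for light-induced genes, near the preset 0.01, yet camera's unadjusted p rose from 7.45e-07 to 0.00782. For root hair markers it was -0.0211, and that p rose from 0.00589 to 0.0464. Other lists had estimates of up to 0.808, and the cause was not tested further. DESeq2 called 6126 genes, 6019 of them shared with edgeR, and limma-voom called 6401. Library size alone gave 6350, with 53.7% of them higher against 50.1% after TMM. Other scaling, filter and GC settings gave 6242 to 6535.

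The replicate numbers showed no clear pairing of the samples: deviations of same-numbered libraries correlated at only 0.002, 0.015 and 0.016. Still, 4 of 6 libraries correlated best with their own number, so pairing stays undecided. With the replicate block 6161 genes were called, 6001 of them shared.

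Of 1340 alternative values for 79 named genes, 1323 kept direction and call, 16 lost the call, 1 gained it and 0 reversed, and 7 genes changed call anywhere. Most named genes were picked for passing the threshold, as 78 of the 79 did, so this stability was largely built in. Over all genes, 4775 of the 6413 calls were kept without gi-2 replicate 1, the fewest with 1 library left out. The most, 5781, were kept without Col-0 replicate 1. Direction turned only for lists that did not pass in either setting, and the cause was not tested. For flowering repressors this was with a mean CPM of at least 1 (adjusted p = 0.947), without Col-0 replicate 1 (0.923; 0.807 to 0.939 with 1 left out), without both doubted libraries (0.928), with GC and length offsets (0.977), with these and the block (0.918), and in fry (0.401). For jasmonate genes it was without gi-2 replicate 3 (0.968; 0.775 to 0.968 with 1 library left out), and for cell cycle genes without Col-0 replicate 1 (0.902; 0.361 to 0.902 with 1 left out) or both doubted libraries (0.928). Starch (0.283) and reactive oxygen genes (0.499) turned in fry. At this depth genes without counts, such as FT and FKF1 in Col-0, allow no more than a bound. Fold changes of genes near the floor of 3 counts, such as AT1G26790 and MYB29 in gi-2, are uncertain in size.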

Other observations

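All tests of explanations in this part, and the annotation terms, were chosen after the results were seen. Among 322 annotation terms of 10 to 300 tested genes, 38 were lower and 8 higher in gi-2 by camera with the preset correlation, and 0 with an estimated one, where 20 had an unadjusted p under 0.05. Genes annotated to the cytosolic ribosome were lower in 77 and higher in 5 of 139 cases (camera adjusted p = 3.00e-08; adjusted p = 0.555 with an estimated correlation). The subunits have terms of their own, which are not a breakdown of these 139 genes. Of 97 large subunit genes 72 were lower and 0 higher (median log2 fold change -0.38, camera adjusted p = 1.65e-12, and 0.551 with an estimated correlation). Of 77 small subunit genes 47 were lower and 0 higher (median -0.33, camera adjusted p = 6.75e-10, and 0.551 with an estimated correlation). Of 99 ribosome biogenesis genes 59 were lower and 0 higher (camera adjusted p = 3.91e-11; adjusted p = 0.551 with an estimated correlation). Ribosomal protein genes have close paralogs, so single members are uncertain.

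Among terms for the plastid, all of nuclear genes, 178 of 287 chloroplast stroma genes were lower and 30 higher (median -0.38; camera adjusted p = 3.91e-11; adjusted p = 0.551 with an estimated correlation), 78 of 108 thylakoid genes were lower and 8 higher (camera adjusted p = 5.26e-12; adjusted p = 0.551 with an estimated correlation), and of 96 genes annotated to the plastid as such 35 were lower and 8 higher (camera adjusted p = 0.00555; adjusted p = 0.551 with an estimated correlation). Of 32 plastoglobule genes 12 were lower and 1 higher, and that term did not pass (camera adjusted p = 0.0925). Of 53 genes of the response to heat, 22 were lower and 5 higher (camera adjusted p = 0.0181; adjusted p = 0.551 with an estimated correlation). Terms that went up included starch catabolic process, with 8 of 10 genes higher and 1 lower (camera adjusted p = 0.00699; adjusted p = 0.551 with an estimated correlation), fatty acid beta-oxidation, with 8 of 18 higher and 1 lower (0.0118; adjusted p = 0.551 with an estimated correlation), and RNA splicing, with 15 of 30 higher and 0 lower (0.0305; adjusted p = 0.551 with an estimated correlation).

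The count of 6413 changed genes was compared with the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1, the real one, gave as many, and the highest of the others gave 0, but 10 splits are too few for a share under 0.05.

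Light-induced genes were lower and starvation-induced genes higher in gi-2 at ZT0. A candidate explanation is that gi-2 seedlings were at an earlier point of the daily clock cycle at harvest. The median log2 fold change of evening clock genes exceeded that of morning clock genes by 2.46, but this restates medians already seen, and genotype, clock phase and harvest time cannot be told apart at a single time point. Another is that Col-0 seedlings received more light before freezing. ELIP1 and ELIP2, which light induces strongly, had 87 counts in Col-0 and 16 in gi-2, a ratio of 6.06 in CPM without TMM scaling (95% interval 3.53 to 11.1). Their level was low in both genotypes, at 1.48 CPM together in Col-0 and 0.245 in gi-2, and neither gene passed the low-count filter. Harvest and genotype coincide, so light before freezing and genotype cannot be told apart.

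Seed transcripts were high in gi-2 replicate 2, where 29 genes exceeded 5 CPM, here without TMM scaling, and 4 times every other library, against 0 to 2 such genes in each other library. For seed remains with the storage transcripts in the proportions of the other gi-2 replicates, 2S albumin and CRU2 counts per 100 CRA1 counts were compared. They were 23.1, 0.0321 and 1.3 in gi-2 replicates 1, 2 and 3 and 0 in every Col-0 library. The ratio of gi-2 replicate 2 thus lay below the range of gi-2 replicates 1 and 3. Those themselves lay far apart, and single libraries cannot decide whether such remains were present. Of 27 of the high genes that were tested, 18 had a product name with words of seeds, embryos or related families, among them OLEO1, OLEO2 and several late embryogenesis genes. Such names were borne by 179 of 19699 tested genes (Fisher's exact test, p = 3.25e-31). The words were chosen after the results were seen and take in broad families such as cupins and lipid transfer proteins, so this p is no independent support. Ungerminated or arrested seeds in that pool may account for the high seed transcripts. But the genes were picked for being high there, so a stress response with the same genes cannot be told apart. Without this library the seed list stayed higher in gi-2 (median log2 fold change 2.65, camera adjusted p = 0.0277), which was not traced to a cause. The call of that list was lost in fry, with an estimated correlation, and without Col-0 replicate 1 or 3.

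Genes changed over 4-fold numbered 228, and 0 of 349 tested genes within 1 Mb of GI were among them, against 1.19% elsewhere (Fisher's exact test, p = 0.0377, odds ratio at most 0.892). Such genes were thus not in excess near GI. Sequence from another parent linked to GI need not change a gene over 4-fold, so this test cannot exclude it. The genes changed over 4-fold formed 9 neighbouring pairs, against a mean of 2.65 in 10000 shuffled gene orders (permutation p = 0.0019), and 8 of the pairs moved in 1 direction. Local variants that change neighbouring genes could give such pairs, but so could tandem copies under shared control such as CBF1 and CBF2, and without sequence reads these cannot be told apart.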
